A study of Homo sapiens with 7 samples.

How the data were processed

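Gene expression was measured in 7 samples of total RNA from 3 human lung epithelial cell lines, 1 array per sample. BEAS-2B, labelled as normal epithelial cells, was measured at 0 h. The carcinoma lines A549 and H322m were each measured at 0 h, 4 h and 24 h of cyclic strain. Per the labels, cells were seeded in strain chambers, and the strain condition was 15% surface distension at 0.5 Hz. Total RNA was extracted with a miRNA-retaining column kit and labelled as biotinylated cRNA, per the labels' protocols. Each sample was therefore measured on a 1-colour array.

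The deposited values were log2 expression values, 1 per probe set and array, made with RMA (background correction, quantile normalization and summarization of probes) per the submitters' processing notes. The version of RMA, the library files and any further filter are not given in the sources used here. The table held 53617 probe sets, and the median of the 7 arrays lay between 2.44 and 2.58. The standard deviation over probe sets ranged from 1.89 in H322m at 24 h to 2.12 in A549 at 24 h. No scanner files, background values or detection calls were used here, and values near the low end of an array have compressed differences, so that a difference with 1 value below its array's median has an uncertain size. In all, 2115 probe sets repeated another probe set's values in every array.

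Probe sets were named through a table of the platform's annotation, with symbols brought up to date through gene IDs, all of which matched the RefSeq gene table. A single gene symbol was found for 16098 probe sets (30.0%), several symbols for 0, and no symbol for 37519, which are unnamed here and were left out of gene counts. The named probe sets covered 14884 genes, of which 11916 were protein-coding, 1398 were long non-coding RNA genes and 1072 were microRNA genes. For the 779 genes with more than 1 probe set, the one with the highest mean over all 7 arrays was used. Control probe sets could not be told apart by their IDs, so the level filter below was computed over all probe sets. ACTB, CCN1, IL6 and CAV1 had no named probe set and are not analysed here.

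A gene was eligible for a comparison when its value lay above the array's own median over all probe sets in at least 1 of the 2 arrays. A difference of at least 1 in log2, or 2-fold, was counted. Each condition had 1 array, so a difference between 2 arrays has no replicate check and no p-value is given for it. The number of arrays limits the precision of every value.

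A total of 30 gene lists with 525 entries was fixed before the data were examined, and 295 entries had a named probe set. They covered immediate-early genes, YAP/TEAD targets, actin and SRF targets, extracellular matrix, TGF-beta response, epithelial junctions, mesenchymal genes, NF-kB and inflammatory genes, interferon-stimulated genes, S phase, G2/M, cholesterol synthesis, the unfolded protein and integrated stress responses, heat shock, NRF2 targets, hypoxia and glycolysis, p53 targets, aryl hydrocarbon receptor targets, mechanosensitive channels and caveolae, EGFR ligands and feedback, histones, ribosomal proteins, oxidative phosphorylation, alveolar and club, basal and squamous, and goblet and ciliated markers, markers of fibroblasts, leukocytes and endothelium, and genes at 9p21. For each list with at least 5 expressed members, the median log2 difference was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A list is said to stand apart when its percentile was under 2.5 or over 97.5, which describes these arrays and is not a test of the condition. Chance gives 1.15 to 1.2 such lists per comparison if genes vary independently. Lists of genes that vary together leave the range more often. On simulated data for A549 at 4 h against 0 h, with 12 genes per list and 10937 genes, 5 of 100 unshifted lists stood apart, 72 of 100 lists shifted by 0.5, and 100 of 100 shifted by 1. The simulated noise was independent between genes, so the 5 of 100 does not show how often lists of co-regulated genes would stand apart.

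Changes shared by the 2 cancer lines were tested with limma (lmFit and eBayes) on the 6 cancer-line arrays, with cell line as a block and time as a factor, and Benjamini-Hochberg adjustment at 0.05. Genes whose mean exceeded the median over all probe sets entered, 10342 in all. The residual of this fit is the disagreement between the lines' time courses, not a spread between replicate cultures. On simulated data with 10342 genes and a noise SD of 0.4, the fit for 4 h recovered 15 of 50 genes planted with a log2 change of 1, 46 of 50 with 2, 50 of 50 with 3 and 50 of 50 with 4, with 10 false calls. The simulated noise was independent and had the same SD in every gene, unlike the real residual. This recovery therefore does not give the power of the test on these arrays. Correlations of log2 differences are across genes, which are not independent replicates. Differences of 4 h and of 24 h in 1 line share the 0 h array, and the value expected with no effect was simulated. This simulation gave the 0 h array the same variance as the 4 h and 24 h arrays.

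The genes named were fixed by rule before the data were examined. For 4 h and 24 h against 0 h in a line, they were the 10 largest differences in each direction of at least 2-fold. Between lines at 0 h, they were the first 5 in each direction. For lists that stood apart, they were the 4 largest members and any that differed 2-fold. Up to 10 genes changed 2-fold in both lines were added, and CDKN2A, MTAP, GAPDH, FOS, EGR1, CCN2, ANKRD1, CXCL8, PTGS2 and PIEZO1. A gene with other expressed probe sets counted among the largest only if as many of these differed in its direction as not. Of the list members and of the last 10 genes that meet this rule, the text gives a part chosen at writing, while all enter the counts of members.

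Alternatives fixed in advance were other level filters, the mean of a gene's probe sets, a further quantile normalization, centring each array on the median of its expressed genes, a 1.5-fold limit, agreement of all expressed probe sets of a gene, random lists without matching, and for the shared fit other filters, no line block, a trended and robust prior, and leaving out each array. An adjustment of log2 differences by loess on mean level (span 0.3) and counts of protein-coding genes alone were added after the data had been seen. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.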

Results

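The series addressed how lung cancer cells respond to prolonged cyclic stretching of their growth surface. A549 is an established lung adenocarcinoma line, H322m a line labelled as carcinoma, and BEAS-2B an immortalized bronchial epithelial line. Each of the 7 conditions was measured once, so the differences below are between single arrays. No unstrained culture was measured at 4 h or 24 h. In every difference between times, strain therefore cannot be told apart from the hours in culture. Between 10157 and 10409 named genes per array lay above that array's median.

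The arrays did not group by line alone. Across 11866 genes, A549 at 4 h and at 24 h correlated with r = 0.981, and they correlated with H322m at 0 h with r = 0.966 and 0.968, but with A549 at 0 h with r = 0.939 and 0.937. A549 at 0 h correlated with H322m at 4 h and 24 h with r = 0.939 and 0.918. By rank it lay closer to A549 at 4 h and 24 h (rho = 0.933 and 0.932) than to H322m at 4 h and 24 h (0.925 and 0.902). H322m at 0 h correlated with H322m at 4 h with r = 0.942 and with H322m at 24 h with r = 0.903. A gap of at least 2-fold separated A549 at 4 h and 24 h plus H322m at 0 h from the other 3 cancer-line arrays in 148 genes, 146 of them lower in the latter, and A549 from H322m in 14, including UPK1B and SAGE1. After quantile normalization these counts were 64 and 17. The spread of values over probe sets was smaller in A549 at 0 h (SD 1.94), H322m at 4 h (2.02) and H322m at 24 h (1.89) than in the other 4 arrays, where it lay between 2.10 and 2.12. The 0 h arrays, whose titles read as strained for 0 h, enter every comparison with 0 h. The comparisons of 24 h with 4 h do without them.

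After 4 h of strain, A549 cells had far higher levels of mechanically responsive and inflammatory transcripts than at 0 h. ANKRD1, a YAP/TEAD target, had a log2 level of 8.13 against 2.39 at 0 h, the latter below the array's median of 2.57, so that the size of its difference is uncertain. CCN2, a matricellular growth factor gene and YAP/TEAD target, was 12.1-fold higher (8.11 against 4.52). All 12 expressed YAP/TEAD targets were higher, 8 of them at least 2-fold, including FJX1 (log2 difference 2.66) and the receptor tyrosine kinase gene AXL (2.56). The list's median difference of 1.33 lay at the 100th percentile of random lists, against a median of 0.21 over all eligible genes.

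Chemokine genes were among the higher transcripts in the same comparison. Of 14 NF-kB and inflammatory genes, 8 were at least 2-fold higher, with CCL20 at 2.99, CCL2 at 2.52, NFKB2 at 2.42 and ICAM1 at 1.72, and the list's median of 1.21 stood apart. PTGS2, which encodes an inducible prostaglandin synthase, was higher by 1.16, and CXCL8 differed by 0.48. EGFR ligands and feedback genes stood apart with a median of 1.74: EREG (2.90), DUSP4 (2.02), HBEGF (1.94), ETV4 (1.82) and SPRY4 (1.74) were each at least 2-fold higher, 5 of 9 expressed members. Actin and SRF targets, including VCL (1.87), TGFB1I1 (1.78) and TPM1 (1.48), stood apart with a median of 0.80 and 5 of 13 members at least 2-fold higher.

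Several metabolic and growth lists were higher too. Of 13 genes of the unfolded protein and integrated stress responses, 8 were at least 2-fold higher (median 1.05), with SESN2 at 2.17, VLDLR at 1.85, PSAT1 at 1.76 and DDIT4 at 1.68. All 19 S-phase genes were higher, 6 at least 2-fold (median 0.85), led by MCM7 (1.26) and CDT1, while G2/M genes lay within the range of random lists (median 0.11). NRF2 targets stood apart (median 0.79), with OSGIN1 at 1.88 and SRXN1 at 1.36 but HMOX1 at -1.18. The p53 targets stood apart in the lower direction (median -0.44), with TP53INP1 at -1.80 and GDF15 at -1.07, whereas AEN (1.31) and PLK3 (1.17) were higher.

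Other large differences at 4 h in A549 included MIR221 (4.18), MAMLD1 (3.65), TRIML2 (3.61), the poliovirus receptor gene PVR (3.36), MIR1204 (3.28), LINC00707 (3.15), MAP3K14, an NF-kB-inducing kinase gene (3.05), and NAV3 (3.05). The lowest relative to 0 h were small Cajal body RNAs, namely SCARNA11 (-6.41), SCARNA4 (-3.64), SCARNA3 (-3.42), SCARNA20 (-3.05), SCARNA6 (-2.48) and SCARNA8 (-2.33), with APOD (-2.90), MIR4534 (-2.29), RASSF9 (-2.27) and MIR574 (-2.24). Immediate-early genes went both ways (11 of 17 higher, within the range of random lists): DUSP5 (2.25), FOSL1 (1.95), ATF3, MYC and JUN (1.52) were at least 2-fold higher, and FOS (-2.23), EGR1 (-1.96) and FOSB (-1.03) lower. PIEZO1, a stretch-activated channel gene, was higher by 1.26. GAPDH lay at 6.36 against 6.21.

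In all, 1610 of 10937 eligible genes differed at least 2-fold between A549 at 4 h and 0 h, 1340 higher and 270 lower. The split depended on scaling: 83.2% were higher as deposited, 62.2% after a further quantile normalization, 37.9% with each array centred on its expressed genes, and 61.3% after adjustment by loess. Centring moved the median difference from 0.21 to -0.18. The size of list medians depended on scaling as well. That of actin and SRF targets went from 0.80 to 0.55 after quantile normalization, 0.53 after loess adjustment and 0.40 after centring.

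At 24 h, A549 cells had higher levels of cell cycle genes and lower levels of immediate-early genes than at 0 h. All 19 S-phase genes were higher, 14 of them at least 2-fold (median 1.32), including GINS2 (1.82), the helicase genes MCM7 (1.64) and MCM5 (1.59) and MCM3 (1.52), and CCNE1 (1.46). Of 19 G2/M genes, 18 were higher and 7 at least 2-fold (median 0.91), with CDK1 at 1.69, CDC20 at 1.41 and PLK1 at 1.27. EGR1 was lower by a log2 difference of -4.68, FOSB by -3.54 and FOS by -2.84, and the immediate-early list stood apart (median -0.34, 5 of 17 at least 2-fold lower). Stress response genes remained among those standing apart (median 1.16), with PSAT1 at 2.02 and PHGDH at 1.60 against DDIT3 at -1.18.

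ANKRD1 and CCN2 at 24 h differed from 0 h by 0.23 and 0.19, and CXCL8 was lower by -1.32. The p53 list stood apart below (median -0.22, TP53INP1 at -1.45), as did TGF-beta response genes (-0.19) and NF-kB genes (-0.11). These latter 2 calls were lost when the random lists were not matched on level, TGF-beta also with probe sets averaged, and NF-kB also after quantile normalization and after loess adjustment. The largest differences included TRIML2 (3.37), PVR (3.21), ELOF1 (3.20), the endonuclease gene APEX2 (3.16), RPL23AP82 (3.08), the kinetochore gene SKA1 (2.97), PMS2CL (2.95), ATG16L1 (2.72), RRN3 (2.70) and MIR221 (2.69), and on the lower side SCARNA11 (-7.40), SCARNA3 (-3.50), SCARNA20 (-3.21), SCARNA4 (-2.83), APOD (-2.82), MIRLET7A1 (-2.46) and SCARNA6 (-2.38). Of 10929 genes, 1841 differed at least 2-fold, 1509 higher and 332 lower. Of these 82.0% were higher, against 58.5% after quantile normalization, 32.6% after centring and 56.6% after loess adjustment, which gave 1207 genes.

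Between 4 h and 24 h in A549, which leaves out the 0 h array, the YAP/TEAD and inflammatory genes were lower at the later time and proliferation genes higher. All 12 YAP/TEAD targets were lower at 24 h (median -0.49, percentile 0.01), with ANKRD1 at -5.52, CCN2 at -3.41 and AMOTL2 at -1.69. All 14 NF-kB and inflammatory genes were lower (median -0.67), including CCL20 (-3.86), CCL2 (-2.34), CXCL8 (-1.80) and PTGS2 (-1.10). Immediate-early genes were lower too, with 7 of 17 at least 2-fold (EGR1 -2.73, FOSB -2.51, FOSL1 -2.34), and the list of EGFR ligands and feedback genes stood apart below (median -0.39) with 5 of 9 members lower, 2 of them at least 2-fold: the ligand gene HBEGF (-2.29) and the receptor gene EGFR (-1.05). All 19 S-phase genes (median 0.47), all 19 G2/M genes (0.75; HMMR 1.24) and all 8 heat shock genes (0.50) were higher. The TGF-beta list (SMURF2 -1.52), the actin and SRF list (TPM1 -1.41) and the hypoxia list (ADM -1.36) also stood apart below, the actin and SRF list not against random lists without matching and the hypoxia list not after quantile normalization. This comparison gave 221 genes at least 2-fold different of 10655, 66 higher and 155 lower.

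**Figure D1:**
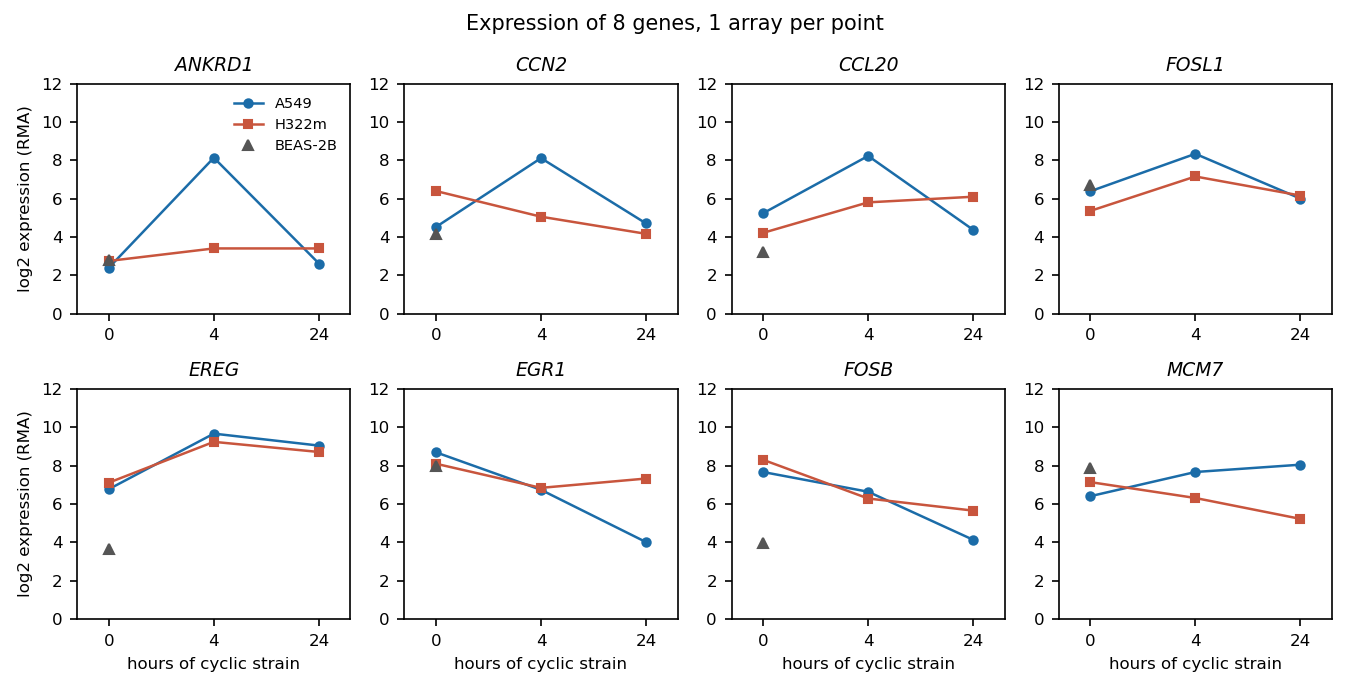
Log2 expression (RMA, y axis) of 8 genes against hours of cyclic strain (x axis) in A549 (circles), H322m (squares) and BEAS-2B at 0 h (triangles), 1 array per point. ANKRD1 stood at 8.13 in A549 at 4 h and at 2.39 and 2.62 at 0 h and 24 h. EREG was higher at 4 h and 24 h than at 0 h in both lines.

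H322m cells at 4 h had higher levels of a few chemokine and transcription factor genes and lower levels of stress response genes than at 0 h. SNAI2, an epithelial-mesenchymal transition factor gene, was 5.09-fold higher (log2 difference 2.35), and the mesenchymal list stood apart (median 0.43), although SNAI2 was its only member at least 2-fold higher. NF-kB and inflammatory genes stood apart above (median 0.30), with CXCL3 at 1.86, CCL2 at 1.62, CCL20 at 1.59 and CXCL8 also at least 2-fold higher. Of 13 genes of the unfolded protein and integrated stress responses, 12 were lower (median -0.89), including DDIT4 (-1.84), PSAT1 (-1.62), PHGDH (-1.44) and SESN2 (-1.40). Mechanosensitive channel and caveola genes were lower (median -1.01, 4 of 7 at least 2-fold), with CAVIN1 at -1.81 and the channel gene PIEZO2 at -1.54, while PIEZO1 differed by -0.81.

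Immediate-early genes stood apart below in H322m at 4 h (median -0.67, 8 of 17 at least 2-fold lower), with FOSB at -2.02, JUN at -1.92 and IER2 at -1.76 but FOSL1 at 1.80, a list call lost with probe sets averaged. CCN2 was lower by -1.34, ANKRD1 differed by 0.65, and the YAP/TEAD list lay just inside the range of random lists (median -0.52, percentile 3.22) and below it after quantile normalization and after loess adjustment. Heat shock genes (HSPA1A -1.51) and goblet and ciliated markers (SPDEF -2.02, but TFF1 1.54) stood apart below, the former not against random lists without matching and the latter not without a filter on low values. NRF2 targets (HMOX1 -1.94, TKT -1.42), actin and SRF targets (TLN1 -1.23, VCL -1.14), TGF-beta response genes (SMAD7 -1.79, but SMURF2 1.30) and interferon-stimulated genes (OASL -1.33) did so as deposited but not after quantile normalization. NRF2 was also lost without matching, the other 3 after loess adjustment, and actin and TGF-beta with probe sets averaged. The largest differences were MIR4521 (3.33), PIP (2.90), F2RL2 (2.82), MIR221 (2.81), UPK1A (2.76), MIR181B1 (2.76), SNAI2, MIR644A (2.32), MIR1206 and STAMBPL1 (2.26) above, and MIR3189 (-3.57), MEX3D (-3.20), BAAT (-3.04), SUCNR1 (-2.86), COQ8B (-2.81), HSD17B14 (-2.76), DOK4 (-2.66), TMEM238 (-2.62), GTF2IRD1 (-2.62) and CFI (-2.55) below. In all, 1497 of 10841 genes differed at least 2-fold, 393 higher and 1104 lower. The share higher was 26.3%, against 36.3% after quantile normalization, 65.9% after centring and 43.3% after loess adjustment.

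At 24 h, H322m cells had lower levels of stress response and immediate-early genes and higher levels of mitotic and chemokine genes than at 0 h. All 13 unfolded protein and integrated stress response genes were lower (median -1.24), 9 at least 2-fold, led by DDIT4 (-2.23) and PSAT1 (-1.82). These values rest on the H322m 0 h array. Against the A549 0 h array, PSAT1 would be at -0.91 and SESN2 at -0.70, but DDIT4 at 0.02 and VLDLR at 0.96. DUSP1 was lower by -3.11, FOSB by -2.65 and JUN by -2.33 (list median -0.94, 16 of 17 lower), a list call lost after quantile normalization, after loess adjustment and with probe sets averaged. Of 19 G2/M genes, 14 were higher against an overall median of -0.27, with HMMR at 1.59 and TTK at 1.58 but KIF20A at -1.29. CXCL3 was higher by 2.67, CCL20 by 1.88 and CXCL8 by 1.35 (list median 0.26), whereas NFKB2 was lower.

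Mechanosensitive channel and caveola genes stood apart below at 24 h in H322m (median -1.41), with CAVIN1 at -1.78, PIEZO2 at -1.63 and PIEZO1 at -1.41. CCN2 was lower by -2.23. FOS was lower by -1.43 by its main probe set but differed by 0.76 when its probe sets were averaged. The largest differences were MIR4521 (4.48), MIR4500 (4.16), PIP (3.68), VTRNA1-1 (3.31), MIR539 (2.81), MNS1 (2.68), CXCL3, SKA3 (2.66), TFF1 (2.64) and THAP10 (2.64) above, and MIR5047 (-3.91), RND1 (-3.79), ANXA9 (-3.73), MIR27B (-3.54), RRAS (-3.48), EXOSC5 (-3.47), DCAKD (-3.38), MIR622 (-3.35), SAT2 (-3.33) and BAAT (-3.30) below. Of 10963 genes, 2697 differed at least 2-fold, 527 higher and 2170 lower. The share higher was 19.5%, against 41.0% after quantile normalization, 63.8% after centring and 47.2% after loess adjustment. Centring moved the median from -0.27 to 0.24.

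From 4 h to 24 h in H322m, G2/M genes were again higher, 18 of 19 (median 0.43), with HMMR at 1.17 and CDC20 also at least 2-fold higher. S-phase genes stood apart above (median 0.08 against -0.34 in random lists), with CDT1 at 0.91 but MCM7 at -1.09, a call lost without matching. Interferon-stimulated genes stood apart above (median 0.53, 1 of 13 at least 2-fold), IFIT3 being higher by 1.08, a call lost without a filter on low values. In total 1273 of 10903 genes differed at least 2-fold, 366 higher and 907 lower. The share higher was 28.8%, against 48.2% after quantile normalization, 58.1% after centring and 48.1% after loess adjustment.

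**Figure D2:**
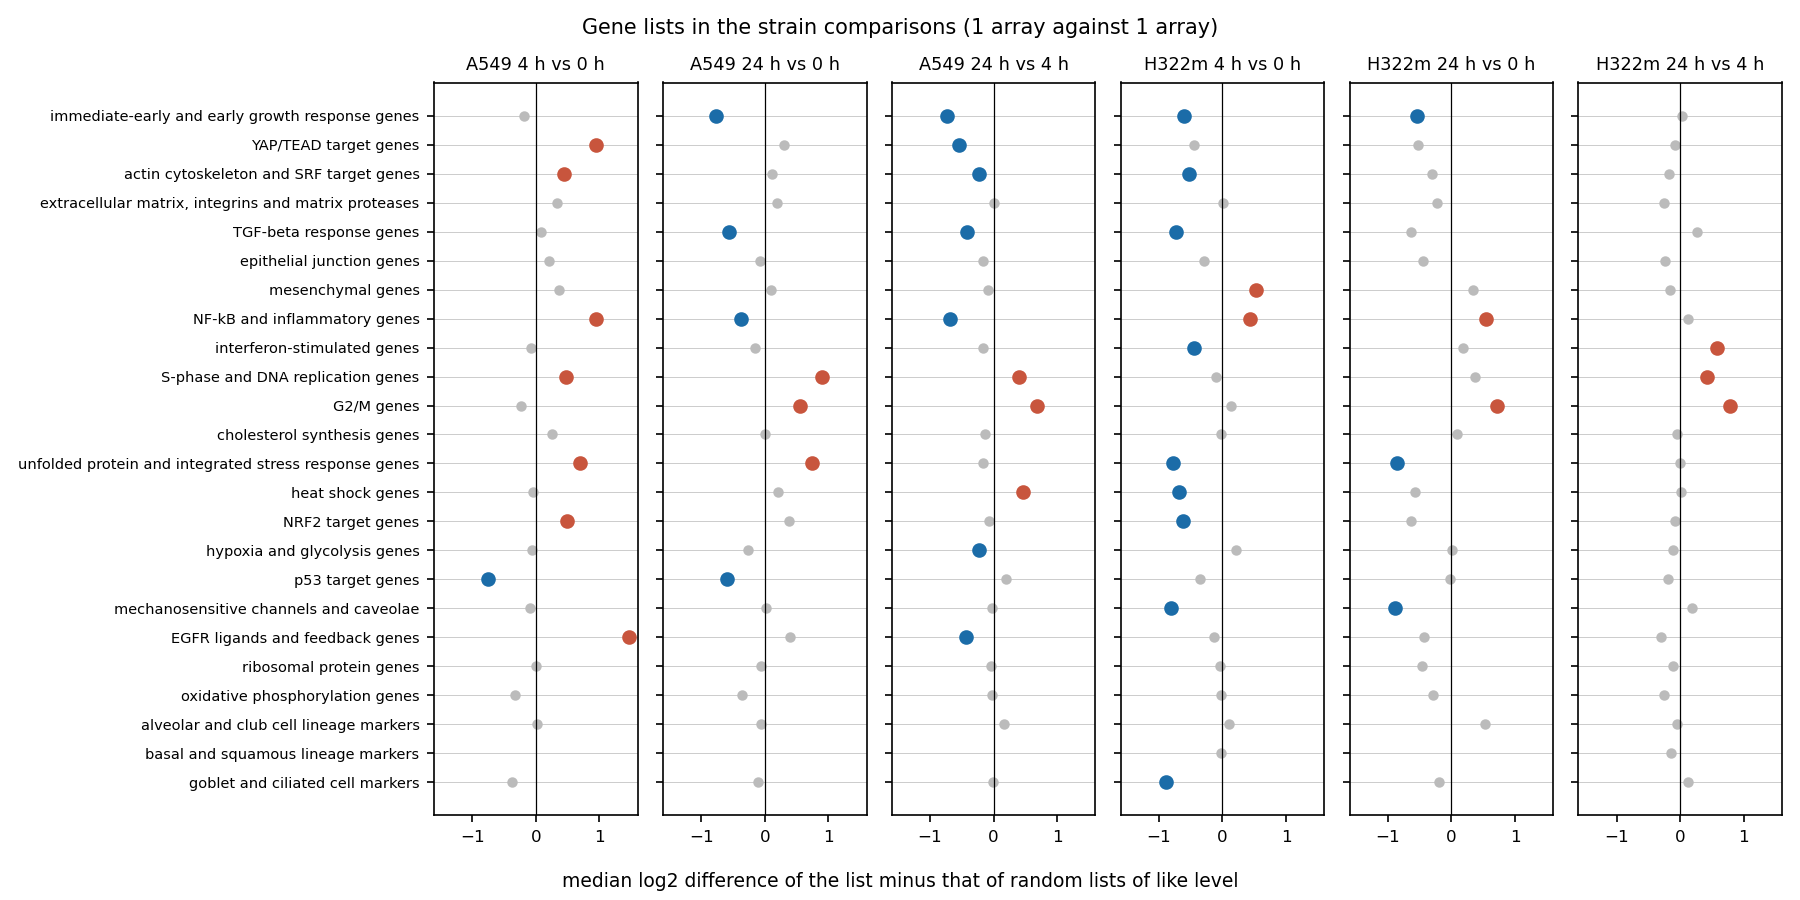
Median log2 difference of each gene list minus that of random lists of like level (x axis) for the 6 comparisons within a cancer line. Larger red and blue points stand apart above and below, and grey points lie within the range of random lists. G2/M genes stood apart above in both lines at 24 h against 4 h.

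Genes that differed 2-fold in the same direction in both cancer lines included the growth factor gene EREG and, in both directions, AP-1 genes at 4 h. EREG, an EGFR ligand gene, was higher by 2.90 in A549 and 2.13 in H322m, FOSL1 by 1.95 and 1.80, TMEM158 by 2.27 and 1.74, and STAMBPL1 by 2.44 and 2.26. MIR221 (4.18 and 2.81), MIR4521 (2.77 and 3.33), MIR1206, MIR644A and LINC00941 were also higher, and SCARNA11 was lower (-6.41 and -2.11). The AP-1 genes FOSB (-1.03 and -2.02) and, by its main probe set, FOS (-2.23 and -1.52) were lower in both lines, although FOS in H322m differed by -0.37 with its probe sets averaged. At 24 h, SKA1 (2.97 and 2.37), MNS1 (2.10 and 2.68), C18orf54 (2.13 and 1.68) and MIR4521 (2.06 and 4.48) were higher, whereas FOSB (-3.54 and -2.65), the ephrin gene EFNA1 (-1.90 and -2.01), WEE2-AS1 (-2.33 and -2.70), PRG4 (-1.69 and -2.12), MIR4675 and SCARNA11 were lower. The number of genes changed in the same direction in both lines was near or below that of independent lists, as given below.

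No gene passed the limma test of a change shared by the lines: 0 of 10342 at 4 h and 0 at 24 h by Benjamini-Hochberg adjusted p. At an unadjusted p under 0.05 there were 215 and 270 genes, fewer than the share of 0.05 that tests with no effect would give. Since disagreement between the lines forms the residual, 0 calls do not show that shared changes were absent. Adjusted over the list alone, 1 gene of the fixed lists was called at 4 h (EREG, limma adjusted p = 0.00636) and 4 at 24 h, with EREG among the EGFR ligands (0.0227) and FOSB lowest among the immediate-early genes (0.0217). This adjustment was made separately in each of 29 lists at each time, with none over the lists, so some calls would arise by chance. Leaving out the A549 0 h array gave 452 and 985 calls, and leaving out the H322m 0 h array gave 728 and 310, with the change from 0 h then resting on the 1 remaining 0 h array.

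Across genes, the changes in the 2 lines ran in opposite directions more often than in the same. The correlation of log2 differences was r = -0.207 (rho = -0.224, 11328 genes) at 4 h and r = -0.332 (rho = -0.356, 11441 genes) at 24 h. At 24 h, 662 genes were at least 2-fold higher in A549 and lower in H322m, where independent lists would share 308. Higher in both were 58 (61.3 if independent) and lower in both 31 (55.9). At 4 h these numbers were 329 (138 if independent), 52 (46.3) and 21 (22.9). From 4 h to 24 h, without the 0 h arrays, r was 0.0737. Within lines, the changes at 4 h and 24 h had r = 0.841 in A549 (covariance 0.391) and r = 0.676 in H322m (covariance 0.371). A shared array that varied only as 4 h and 24 h do would give covariances of 0.0753 and 0.197 with no effect. The 0 h arrays may vary more. A549 at 0 h lay at least 2-fold below both other A549 arrays in 961 genes and above both in 171. These numbers were 12 and 106 at 4 h and 18 and 30 at 24 h. How much of the covariance comes from the shared array is therefore not known.

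**Figure D3:**
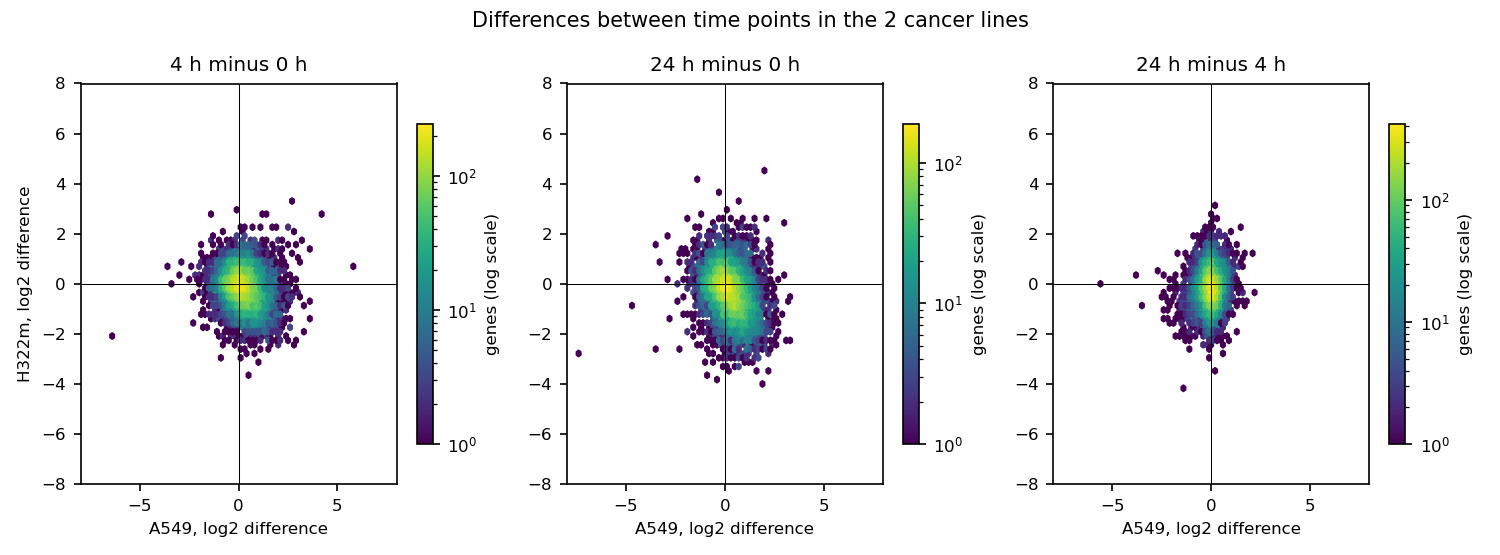
Log2 difference of each expressed gene in H322m (y axis) against A549 (x axis) for 4 h minus 0 h, 24 h minus 0 h and 24 h minus 4 h, with colour giving the number of genes per hexagon on a log scale. The cloud slopes downward at 24 h minus 0 h (r = -0.332) and shows little slope at 24 h minus 4 h (r = 0.0737).

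At 0 h, both cancer lines had much lower levels of epithelial junction, basal and interferon-stimulated genes than BEAS-2B. EPCAM, an epithelial adhesion gene, lay at 10.20 in BEAS-2B, 5.30 in A549 and 6.09 in H322m, and the splicing factor gene ESRP1 was lower by -6.32 and -6.22. Of 16 junction genes, 12 in A549 and 11 in H322m were at least 2-fold lower (medians -2.49 and -2.39), including CLDN7, ST14, GRHL2 and KRT19, whereas KRT18 was higher by 1.34 in H322m. All 16 expressed interferon-stimulated genes were lower in both lines (medians -2.60 and -2.58), with CXCL10 at -4.92 and -5.30. No reference profile of either line was used here, so whether the arrays labelled H322m are that line could not be checked. The basal genes DSG3 (-5.89 and -6.15) and KRT5 (-4.80 and -5.01) were lower, and so were matrix genes, with TNC at -6.23 and -6.17 and MMP14 at -5.99 and -5.25.

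Antioxidant NRF2 targets were higher in the cancer lines than in BEAS-2B, and so were several genes near the low end of the BEAS-2B array, for which the size and order of differences are uncertain. FGA, a fibrinogen chain gene, lay at 9.12 in A549 and 9.10 in H322m against 2.05 in BEAS-2B, and CNTN1 at 9.46 and 9.34 against 2.73. APOH (8.93), NTS (8.39) and CP (8.65) were among the named genes in A549, and TM4SF20 (9.02), TM4SF4 (9.87) and CCL2 (8.54) in H322m. All 8 NRF2 targets were higher in both lines (medians 1.13 and 1.66), with PGD at 2.20 and 3.08 and GSR also at least 2-fold higher. Goblet markers (AGR2 2.88 and 3.36, SPDEF 2.10 and 3.68) and oxidative phosphorylation genes (medians 0.53 and 0.66) stood apart above, goblet markers in neither line without a filter on low values, and oxidative phosphorylation genes in H322m not after quantile normalization or loess adjustment. NF-kB genes (CXCL5 4.23, but ICAM1 -5.65) and p53 targets (median 0.29, not without matching) stood apart above in A549, and ribosomal protein genes (median 0.62, RPS19 1.29) in H322m.

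Proliferation genes were lower in the cancer lines than in BEAS-2B, with S-phase medians of -1.32 and -0.90 and CCNE2 at -3.26 and -2.81. All 19 G2/M genes were lower in both (medians -0.80 and -0.98), a call lost in A549 after quantile normalization and after loess adjustment. UCA1 (-7.04 and -7.38), MIR205 (-6.83 and -6.96) and S100A7 (-6.35 and -6.75) were lower, with values near the low end in the cancer lines that leave the sizes uncertain. CDKN2A lay at 4.83 in BEAS-2B and between 1.96 and 2.96 in the 6 cancer-line arrays, and MTAP, its neighbour at 9p21, at 5.83 and between 3.98 and 4.96. At least 2-fold differences from BEAS-2B numbered 3290 of 11136 genes in A549 (850 higher, 2440 lower) and 2275 of 10960 in H322m (979 higher, 1296 lower). In A549 25.8% were higher, against 44.7% after quantile normalization, 62.6% after centring and 44.8% after loess adjustment.

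FBN2, which encodes a microfibril protein, was higher in H322m than in A549 at 0 h, and UPK1B, a uroplakin gene, was lower. H322m was higher in FBN2 (3.54), BAAT (3.45), CFI (3.42), DEDD2 (3.21) and PVR (3.21), and A549 in UPK1B (-3.81), APOD (-3.25), F2RL2 (-3.23), SAGE1 (-3.04) and SCARNA20 (-2.54). An exchange of the 0 h arrays, which is not excluded, would reverse every direction in this comparison. G2/M genes were the only list to stand apart as deposited, lower in H322m (median -0.17, NUSAP1 -0.79, HMMR -0.60). YAP/TEAD targets lay above after quantile normalization and loess adjustment, and unfolded protein and integrated stress response genes against random lists without matching. Of 10966 genes, 1531 differed at least 2-fold, 1269 higher and 262 lower in H322m, more than the 573 between A549 at 4 h and H322m at 0 h. The share higher was 82.9%, against 61.5% after quantile normalization, 33.5% after centring and 59.5% after loess adjustment.

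Some lists gave no difference that stood apart within a line. Cholesterol synthesis, extracellular matrix, epithelial junction, ribosomal protein, oxidative phosphorylation and alveolar lists lay within the range of random lists in all 6 comparisons within cancer lines, and basal markers in the 2 where enough were expressed. Extracellular matrix genes in A549 at 24 h against 0 h left that range without a filter on low values, and ribosomal protein genes in H322m at 24 h against 0 h without matching. No histone gene had a named probe set, and of the aryl hydrocarbon receptor list TIPARP alone did, higher by 1.03 in H322m at 4 h and lower from 4 h to 24 h in both lines (-1.09 in A549, -1.07 in H322m). Of other cell types, fibroblast markers LUM, DCN and THY1 lay between 1.23 and 4.26, and the 6 endothelial markers between 1.31 and 3.48. The leukocyte marker CD68, which epithelial lines can express, lay between 7.51 and 9.17 and was higher at 4 h than at 0 h by 1.06 in A549 and 1.21 in H322m, and CD14 between 3.39 and 5.53.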

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

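All tests of explanations in this part were chosen after the results had been seen, with their bounds. Differences between the lines in this part were not tested, since each rests on 1 array per line and time. Lists are given that stood apart on opposite sides in A549 and H322m, and named genes that differed from 0 h at least 2-fold in opposite directions.

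Stress response and cytoskeletal lists differed in direction. The median change of unfolded protein and integrated stress response genes was larger in A549 than in H322m by 1.93 at 4 h and 2.40 at 24 h. For actin and SRF targets the gap was 1.44 and for NRF2 targets 1.40, both at 4 h. For NF-kB and inflammatory genes at 24 h it was -0.37. For these last 3 lists the call in 1 line was lost under some alternatives, as given above: actin and SRF and NRF2 targets in H322m, and NF-kB in A549.

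Single genes with opposite 2-fold changes at 4 h are given by the A549 change minus the H322m change. PVR had 5.24, CCN2 4.93, CAVIN1 4.46, AXL 4.23, TMEM238 4.14, GTF2IRD1 3.65, SESN2 3.57, DDIT4 3.52, JUN 3.44 and PSAT1 3.38. DUSP4 had 3.25, SMAD7 3.14, ETV4 3.10, VCL 3.00, PHGDH 2.75, BAG3 2.56, AEN 2.53 and MCM5 2.52. UPK1A had -4.08, being lower in A549 and higher in H322m.

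At 24 h the same gap was 5.77 for MIR5047, 5.69 for MIR27B, 5.50 for APEX2, 5.50 for PVR, 5.02 for EXOSC5, 4.29 for ATG16L1, 4.14 for PMS2CL and 4.07 for MIR221. CAVIN1 had 3.88, PSAT1 3.84, DDIT4 3.76, MCM7 3.56, CCNE1 2.96, MCM5 2.88, SMAD7 2.85, VLDLR 2.74 and NFKB2 2.70. SESN2 had 2.60, PIEZO1 2.49, SMURF1 2.46 and AEN 2.15. The gap was negative for MIR4500 (-5.58), SCARNA3 (-5.07), SCARNA4 (-4.81), MIR539 (-4.05) and CXCL8 (-2.67).

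These gaps, and those of the lists, hold for the 0 h arrays as labelled. List medians with these arrays exchanged are not given here. With the 0 h arrays exchanged, the gap would have the same sign in 14 of 19 genes at 4 h and in 18 of 26 at 24 h, and 0 and 2 genes (CXCL8 and MIR4500) would differ 2-fold in opposite directions. At 4 h AXL would have 0.89, JUN -0.81 and PVR -1.18. The genes were picked for opposite directions under the labels, so smaller gaps under another arrangement follow from that choice and do not weigh for an exchange.

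Probe sets with no gene name, outside all comparisons above, also differed: 615 were at least 4-fold higher and 252 lower in A549 at 4 h than at 0 h, and 684 higher and 242 lower at 24 h. In H322m 250 were higher and 339 lower at 4 h, and 441 higher and 941 lower at 24 h.

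The opposite directions in the 2 lines may be technical or biological. Quantile normalization left a correlation of -0.229 at 24 h, which argues against array-wide scale as the whole cause, and change against gene span had rho = 0.127 in A549 and -0.041 in H322m, which argues against a span bias. An exchange of the 0 h arrays between the lines stays open. A 2-fold gap separated A549 at 4 h and 24 h plus H322m at 0 h from the other 3 cancer-line arrays in 148 genes. Of these, 146 were lower in those 3 arrays, which have the smallest spread. A gap of that size followed the labels in 14 genes. After quantile normalization these counts were 64 and 17, and the 8 other splits gave at most 3 either way. At 4-fold, 2 genes followed the exchange and 5 the labels, and 1 and 5 after quantile normalization. After quantile normalization, A549 at 0 h differed 2-fold from A549 at 4 h and 24 h in 1198 and 1314 genes. It differed from H322m at 4 h and 24 h in more, 1350 and 1992. With the 0 h arrays exchanged, 2-fold differences would number 573 rather than 1610 (4 h) and 541 rather than 1841 (24 h) in A549, and 1431 rather than 1497 (4 h) and 1654 rather than 2697 (24 h) in H322m; after quantile normalization, 530 rather than 1198, 470 rather than 1314, 1350 rather than 1310 and 1992 rather than 2347. An exchange and a difference between the lines in response to strain cannot be told apart here, because at 2-fold some genes, such as UPK1B and SAGE1, follow the labels and more, such as APEX2 and DPP3, do not. The first principal component of these arrays held 51.0% of the variance. It placed H322m at 24 h (-0.68) and 4 h (-0.25) and A549 at 0 h (-0.19) opposite H322m at 0 h (0.31) and A549 at 4 h and 24 h (0.41 each). The second component (19.1%) set A549 at 0 h (-0.86) apart from all the others, including H322m at 4 h (0.42) and 24 h (0.22). Another technical difference between the groups of arrays on the first component was not tested and stays open.

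The cancer-line arrays correlated better with each other (r from 0.896 to 0.981) than with BEAS-2B (0.799 to 0.867), although by 2-fold counts some cancer-line pairs lay further apart, with 2852 genes between A549 and H322m at 24 h against 2202 between A549 at 24 h and BEAS-2B. Scale does not account for the correlations, as by rank the lowest between cancer-line arrays was 0.894 and the highest with BEAS-2B 0.862. After quantile normalization, 2991 genes differed at 0 h between A549 and BEAS-2B and 1170 between H322m and A549. The 2-fold counts still went the other way for some pairs. After that normalization, 2344 genes differed between A549 and H322m at 24 h, against 2128 between A549 at 24 h and BEAS-2B. A shared or mixed cell population under the 2 cancer-line labels cannot be told apart from 2 similar lines. Statements on both cancer lines therefore hold for the arrays as labelled. A549 at 24 h differed 2-fold from H322m at 0 h in 541 genes and from A549 at 0 h in 1841, but from H322m at 24 h in 2852. A 2-fold gap separated the labelled lines in 14 genes. A 4-fold gap separated the labelled lines in 5 genes (UPK1B, SAGE1, FILIP1, ANXA10 and CEACAM6, chosen after their values were seen). The arrangement with the 0 h arrays exchanged gave 2 such genes, or 1 after quantile normalization, and the other 8 splits gave at most 1. The identity of the arrays labelled H322m, which were low in EPCAM, ESRP1, GRHL2 and KRT19, could not be checked without a reference profile and stays open. BEAS-2B was at least 2-fold above all 6 cancer-line arrays in 678 genes and below them in 267. At 4-fold these counts were 214 and 100, against the 5 genes between the labelled lines. Setting 1 array apart from 6 is not the same comparison as splitting those 6 by label, so the counts are not on 1 scale.

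The 4 h peak in A549 does not rest on the 0 h array alone, since in the comparison of 24 h with 4 h the YAP/TEAD list lay at percentile 0.01 and the NF-kB and inflammatory list at percentile 0. Handling shared by all 4 h cultures stays open for the inflammatory list, which in H322m lay at percentile 98.84 at 4 h against 0 h, as shared handling would need, but at 78.54 at 24 h against 4 h. It also stays open for the YAP/TEAD list, which in H322m lay at percentile 3.22 at 4 h against 0 h, with 9 of 12 members lower and near the bound that would argue against it (2.09 after quantile normalization and 2.45 after loess adjustment, past that bound), and at 32.22 at 24 h against 4 h. A hypothesis is that the peak may be a transient response to strain, which replicate cultures and unstrained cultures kept for 4 h and 24 h would test. With 1 array, a culture effect specific to that sample cannot be excluded.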

How the results depend on the processing

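The loess adjustment, the protein-coding counts and the quantile-normalized splits of arrays were added after the data had been seen. Under a 1.5-fold limit, which counts more genes by construction, the numbers were 4007 (A549 4 h against 0 h), 4421 (24 h against 0 h) and 1135 (24 h against 4 h), 3948, 5198 and 3795 in H322m, and at 0 h 5821 (A549 against BEAS-2B), 4375 (H322m against BEAS-2B) and 3969 (H322m against A549). The loess adjustment gave 1207 genes for A549 at 24 h, and quantile normalization a correlation between lines of -0.229 at 24 h; the cause was not tested. Every other count of genes at least 2-fold different between 2 arrays stayed within 1.5 times of the value given. Scaling nevertheless moved the direction split where the text gives further shares. It also changed which genes were counted. After centring, A549 kept 812 of 1610 genes at 4 h against 0 h and 874 of 1841 at 24 h. H322m kept 917 of 1497 and 1453 of 2697. After quantile normalization the genes kept numbered 990 and 1051 in A549 and 1213 and 1841 in H322m. The count of genes with a 2-fold gap under an exchange of the 0 h arrays moved from 148 to 64 after quantile normalization, and that under the labels from 14 to 17.

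Of the 463 named differences of at least 2-fold, 399 kept their direction and stayed at least 2-fold after quantile normalization, 371 after centring, 387 after loess adjustment and 454 with probe sets averaged. The 1 reversal was FOS in H322m at 24 h, 0.76 with probe sets averaged; the cause was not tested. Of 66 list calls over all 9 comparisons, 47 held under every alternative and 19 were lost under at least 1, while 15 lists that had not stood apart did so under at least 1. These 15 count endothelial markers in A549 at 24 h against 0 h, which had too few expressed members for a percentile in the main setting. Among these, immediate-early genes in H322m against BEAS-2B at 0 h did so under all 5. A gene's probe sets agreed only in part: r between the differences of 2 expressed probe sets ranged from 0.169 to 0.632.

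The limma test gave 0 calls under every filter, normalization and prior tried, and 0 without the line block (no replicate block). Leaving out 1 array gave 0 to 728 calls at 4 h and 0 to 985 at 24 h, with calls only when a 0 h array was left out. The counts at an unadjusted p under 0.05 (215 and 270) moved more widely, from 107 to 360 at 4 h and from 127 to 443 at 24 h over filters, normalizations and priors, and from 25 to 2177 and from 77 to 2426 on leaving out 1 array. An alternative for cross-hybridising probe sets was not run, because these IDs do not mark them, nor were the control probe sets of ACTB and GAPDH. Without detection calls, signal over background limits every value near an array's median.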

Other observations

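The gene families in this part were chosen after the named genes had been seen, from genes already prominent in the comparisons, so their percentiles describe and do not test them. No explanation is offered for them.

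Most genes of a kinetochore and spindle family, which also held the meiotic recombination gene MND1, were higher at 24 h in both cancer lines. All 13 expressed members were higher in A549 at 24 h than at 0 h (median log2 difference 1.39, 11 at least 2-fold) and 11 of 13 in H322m (median 1.52, 8 at least 2-fold). NDC80 lay at 3.44, 4.69 and 5.77 at 0 h, 4 h and 24 h in A549 and at 4.50, 4.21 and 5.47 in H322m. SKA2 and ZWINT were exceptions in H322m, at 6.18 and 5.19 at 0 h and 5.43 and 4.99 at 24 h. All 13 were lower in A549 at 0 h than in BEAS-2B (median -1.35), and 12 of 13 in H322m (median -1.37).

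A set of 14 genes, chosen mostly for ribosome biogenesis, separated A549 at 0 h from A549 at 4 h and 24 h. It also held POLRMT, a mitochondrial RNA polymerase gene, and GEMIN4, an SMN complex gene. The difference was not particular to this set. Of 11089 genes, A549 at 0 h lay at least 2-fold below both other A549 arrays in 961 and above both in 171. All 14 were higher at 4 h than at 0 h (median 2.18) and all 14 at 24 h (median 2.28), 12 of them at least 2-fold at each time. RRP12 lay at 4.26, 6.80 and 6.55 in A549 and at 5.33, 5.04 and 4.66 in H322m. In H322m the medians were -0.45 at 4 h and -1.02 at 24 h. At 0 h, 13 of the 14 were higher in H322m than in A549 (median 1.37).

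Small Cajal body RNAs ran the other way. Of 23 genes, 20 were lower in A549 at 4 h than at 0 h (median -1.03) and 20 at 24 h (median -1.06), while in H322m 16 of 22 expressed were higher at 4 h (median 0.43) and 16 at 24 h (median 0.90). SCARNA4 lay at 10.60 in A549 at 0 h and 10.27 in H322m at 24 h, and between 6.96 and 9.05 in the other 5 arrays.

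Part of a family of 12 liver-type secreted genes was far higher in the cancer lines than in BEAS-2B. Of 9 expressed at 0 h, 8 were higher in each line, 6 at least 2-fold in A549 and 7 in H322m, while C3 was at least 2-fold lower in both. FGB lay between 6.46 and 8.34 in the 6 cancer-line arrays and at 2.76 in BEAS-2B, and FGG between 5.09 and 7.74 against 1.56. C3 lay between 7.05 and 9.27 against 10.44 in BEAS-2B. ALB and APOB lay at the low end of every array, and TTR (between 3.39 and 4.30 against 3.48) and AHSG (between 1.74 and 2.91 against 1.94) differed less than 2-fold from BEAS-2B in each cancer-line array. CFI was high in 1 array, at 5.11 in H322m at 0 h, 2.55 at 4 h and 1.82 at 24 h, and between 1.69 and 1.76 in A549.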
